A study of Mus musculus with 8 samples.

How the data were processed

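RNA was measured in 8 cultures of neural progenitors made from mouse embryonic stem cells. The stem cell line, A2lox.Cre Bcl6, carries a Bcl6 transgene under a tetracycline-inducible promoter. Per the labels' protocols, the cells were differentiated without added morphogens in a defined medium with 400 ng/ml cyclopamine, an inhibitor of hedgehog signalling, and at day 12 they had received 1 µg/ml doxycycline or DMSO for 24 h. Poly(A) RNA was made into libraries with a stranded TruSeq kit, per the labels' protocols. The labels put 4 cultures in the control group (DMSO) and 4 in the Bcl6-induced group (doxycycline), and number them as differentiations 1 to 4 in each group. No culture with doxycycline and without the transgene was among the samples, so the comparison holds the effects of Bcl6 and of doxycycline together.

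The authors used STAR 2.5.3a, HTSeq 0.9.1 and edgeR 3.20.1 with the mouse genome build mm10, per the submitters' processing notes, which give no role or order. The sources used here do not say whether HTSeq counted by strand. The authors deposited 1 table for the whole series, with 14954 genes. Decimal commas in it had been turned into column breaks, which gave 36 cells per line under 24 header names. All 14954 lines were rejoined and each was matched to its own CPM values. The decimals had lost their leading zeros in this step, so the columns with the authors' statistics could not be read and were not used. Some gene symbols had turned into dates, and 3 symbols occurred more than 1 time. Rows were therefore handled by their Ensembl identifiers, and genes were named by the symbol in the table.

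The expression values the authors deposited are a score and not raw counts: whole numbers that sum to 19.93 M to 19.96 M in every library. They were found to be reads scaled to a common library size and rounded up. In each library the values sat on the multiples of a fixed step, between 1.33 and 2.12, for at least 99.6% of genes, against at most 77.6% when the step was shifted by a few percent. A value counted as a multiple only if rounding it up gave exactly the deposited number. Dividing by the step gave the read totals behind the values. The recovered totals, in M reads, were 9.42, 9.49, 9.74 and 9.54 in controls 1 to 4, and 15.02, 11.04, 11.28 and 10.33 in induced libraries 1 to 4. Every control was thus shallower than every induced library. The fixed plan had assumed raw counts and named edgeR for them, which was not used because the values were not raw counts. For normalized values the plan had named limma.

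The main test was limma 3.58.1 in R 4.3.3 on log2(value + 1), with the trend of variance on expression, no covariate, and Benjamini-Hochberg adjustment over all 14954 genes. A gene was called changed at an adjusted p under 0.05. No filter on low values was applied, since the table held no gene with a mean under 15.1 scaled reads. Fold changes are on the log2(value + 1) scale, with a pseudocount of 1 on values scaled to about 20 M, and understate the change of genes with few reads. Levels are given as CPM, the value divided by its library's total, with the mean ± SD over n = 4 libraries. The labels number the differentiations but do not say more about how far the 4 cultures of a group were independent, so p-values measure the spread between these libraries. The Bcl6 count does not separate the transgene from the endogenous gene.

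The test was tried on simulated data. Counts were drawn for the 14954 genes from the libraries' own means, spread and depths, with 200 genes changed in each of 5 runs of the comparison of induced with control. The limma test recovered 49.6% of genes changed 1.5-fold, 77.5% of those changed 2-fold and 95.6% of those changed 4-fold, and 5.0% of its calls were genes left unchanged. Each gene was drawn independently, so deviations that many genes of a library share were not simulated. The real libraries held such deviations, among them a trend with transcript length in control 1. The simulated shares may therefore not hold for the real data.

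Before the data were examined, 31 gene lists were written from general knowledge: 9 core lists and 22 others, with 472 of their 535 genes in the table. The Notch, Wnt, FGF and Sonic hedgehog lists were put in because the study's paper is known to discuss these pathways, and their members were chosen from general knowledge. For each list the called members were counted, adjusted over all genes and adjusted over the list alone. Camera with a preset correlation of 0.01 compared each list with all other genes, adjusted over the 31 lists, and was repeated with an estimated correlation. None of its calls held with the estimated correlation, under which the smallest adjusted p was 0.41. The fry test, which takes each list without comparing it with other genes, was also run.

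The genes named were fixed by a rule before the data were examined: Bcl6; the 6 largest rises and the 6 largest falls among changed genes with a mean log2 CPM of at least 1 and the same direction in all 4 same-numbered pairs; up to 3 changed members with the smallest p in each core list and up to 2 in each other list; and the fixed genes Hes5, Hes1, Sox2, Pax6, Eomes, Neurog2, Tubb3, Dcx, Tbr1, Mki67 and Ccnd1. Where the text names other list members, they were chosen after their values were seen.

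Gene positions, biotypes, and the length and GC content of each gene's longest transcript came from GENCODE vM21, which uses the same build (GRCm38, called mm10), by Ensembl identifier; 14930 of 14954 identifiers matched (99.84%). Alternatives were other pseudocounts, limma-voom on the recovered reads, a block for the differentiation number, leaving out each library or both libraries of a number, other thresholds, and, added after the data were seen, other scalings, filters, variance models, library weights, thinned reads, and removal of the trend on transcript length and GC. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.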

Results

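The data are 8 RNA-seq libraries of cortical-type neural progenitors differentiated in culture from mouse embryonic stem cells, 4 with Bcl6 induced for 24 h by doxycycline and 4 treated with DMSO as controls. Bcl6 is a transcriptional repressor best known from germinal centre B cells. The comparison asks which genes change when Bcl6 is raised in these progenitors. Expression of 14954 genes was compared, from 9.42 M to 9.74 M reads per control library and 10.33 M to 15.02 M per induced library.

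The libraries of a group were not equally alike. Over 11980 genes the variance between 2 libraries was 2.92 times the sampling variance for induced libraries 1 and 2, the closest pair, and 35.2 times for controls 1 and 3. Induced libraries 3 and 4 were also close, at 3.29 times. Between induced library 1 or 2 and induced library 3 or 4 it was 5.82 to 9.21 times, and between induced library 4 and control 4 it was 6.50 times. Control 1 stood apart from the other controls in a way related to transcript length. The tenth of genes with the longest transcripts lay at a median of -0.43 (log2) from the control mean in this library, and the tenth with the shortest at 0.31. Across 11856 genes, which are not independent replicates, its deviation had a Spearman rho of -0.73 with transcript length, against 0.18, 0.52 and 0.52 in controls 2, 3 and 4. The induced-minus-control fold changes of these genes followed transcript length with a rho of 0.22 (-0.07 without control 1) and GC content with a rho of 0.14 (0.28 without control 1).

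**Figure D1:**
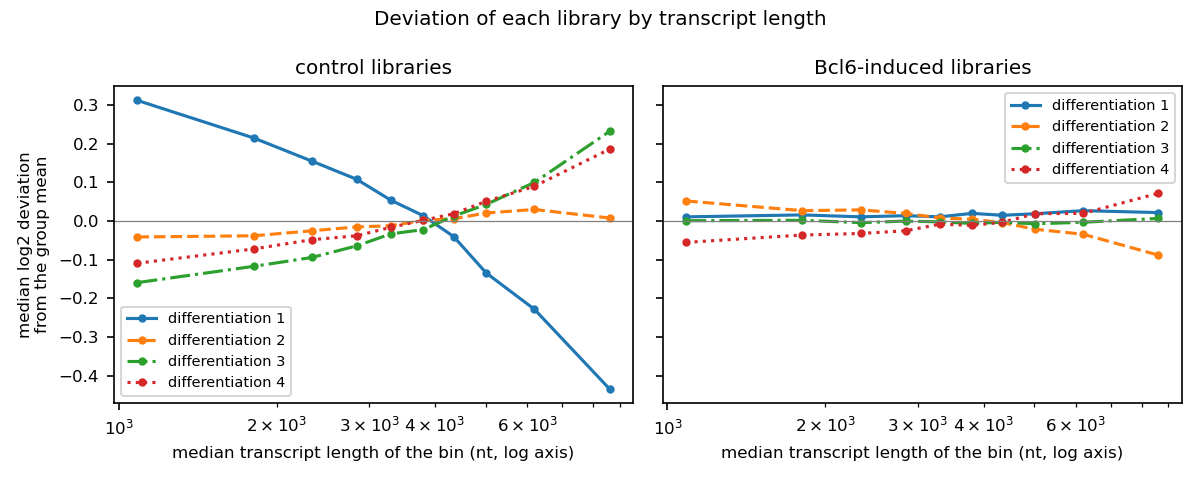
Median log2 deviation of each library from the mean of its group (vertical axis) for 10 bins of genes by transcript length (horizontal axis, log scale), controls at the left and induced libraries at the right, 1 line per library. Control 1 runs from 0.31 in the shortest bin to -0.43 in the longest, while induced libraries stay between -0.09 and 0.07.

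Bcl6 itself (ENSMUSG00000022508, chromosome 16, 23965052 to 23988852, minus strand, mm10) rose from 6.49 ± 0.49 CPM (SD, n = 4) in the controls to 392 ± 47.1 CPM (n = 4) in the induced cultures, a log2 fold change of 5.90 ± 0.10 (SE) with a limma adjusted p of 6.8e-11. Every induced library lay between 325 and 427 CPM of Bcl6 and every control between 6.01 and 7.12 CPM. Changed genes beyond Bcl6 included 9 of 18 radial glia markers and 4 of 22 Notch pathway genes that fell, and 9 of 24 pan-neuronal and 8 of 16 pluripotency genes that rose. No list call by camera held with an estimated correlation (adjusted p = 0.46, 0.59, 0.41 and 0.41 for these lists). In all, 1019 genes changed, 681 of them higher and 338 lower in the induced cultures. They made up 6.8% of all genes tested, the share to read each list's count of called members against. Of the 1019 genes, 166 changed at least 2-fold, 93 higher and 73 lower. The count depended on single libraries: it was 1697 without control 1, 359 without control 2, and 308, 350 and 649 without induced libraries 1, 2 and 3. The excess of higher genes depended on the scaling, with 536 higher and 424 lower under median-of-ratios scaling, 501 and 477 under upper quartile scaling, and 899 and 863 once the trend on transcript length and GC was taken off.

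Among changed genes with a mean log2 CPM of at least 1, the largest rises after Bcl6 were in genes close to silent in the controls. Ly6a, a cell surface antigen of haematopoietic stem cells, rose from 0.48 ± 0.25 to 8.86 ± 0.46 CPM (adjusted p = 0.00024). Cdx2, a homeobox factor of trophectoderm and of the posterior embryo, rose from 1.303 ± 0.572 to 9.48 ± 1.80 CPM (adjusted p = 0.0022). Ptgs1, a prostaglandin synthase, rose from 0.85 ± 0.44 to 5.32 ± 1.54 CPM. Mmp9, a secreted matrix protease, rose from 1.015 ± 0.33 to 5.36 ± 0.96 CPM, and the posterior homeobox gene Hoxd9 from 1.503 ± 0.882 to 4.45 ± 1.31 CPM (all n = 4). The controls held between 1 and 7 reads of Ly6a, whose reads can be shared with close relatives of the Ly6 family. The first 4 of these genes remained called without any 1 library, while Hoxd9 was lost without 5 of the 8, with an adjusted p of up to 0.087 without induced library 1.

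The 6 largest falls were in Hes5, the fatty-acid binding protein of radial glia Fabp7, Pdzph1, the long non-coding RNA C130071C03Rik, the FGF-binding protein Fgfbp3, and Fam181a. Hes5, a Notch target that holds progenitors undifferentiated, fell from 17.3 ± 4.13 to 3.17 ± 3.37 CPM (log2 fold change -3.66 ± 0.95, adjusted p = 0.044). The log2 fold change of Hes5 ranged from -2.85 without induced library 1 to -4.39 without induced library 4. Fabp7 fell from 179.6 ± 28.1 to 46.9 ± 40.9 CPM (-2.53 ± 0.62, adjusted p = 0.036). Pdzph1 went from 4.90 ± 1.49 to 1.14 ± 0.95 CPM, C130071C03Rik from 22.4 ± 0.93 to 6.52 ± 4.99, Fgfbp3 from 46.2 ± 14.2 to 12.4 ± 7.53 and Fam181a from 11.4 ± 1.39 to 3.35 ± 2.38 CPM. These falls had a wide spread among the induced libraries. Hes5 stood at 0.20, 0.30, 6.06 and 6.12 CPM in induced libraries 1 to 4, with 3 reads in each of libraries 1 and 2, and Fabp7 at 9.47, 14, 76.6 and 87.4 CPM. Each of the 6 lost its call when some single library was left out, with adjusted p values of up to 0.13 for Hes5 and 0.11 for Fabp7 (both without induced library 2), 0.082 for Pdzph1 (without induced library 2). It reached 0.082 for C130071C03Rik, 0.052 for Fgfbp3 and 0.063 for Fam181a (these without control 2).

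**Figure D2:**
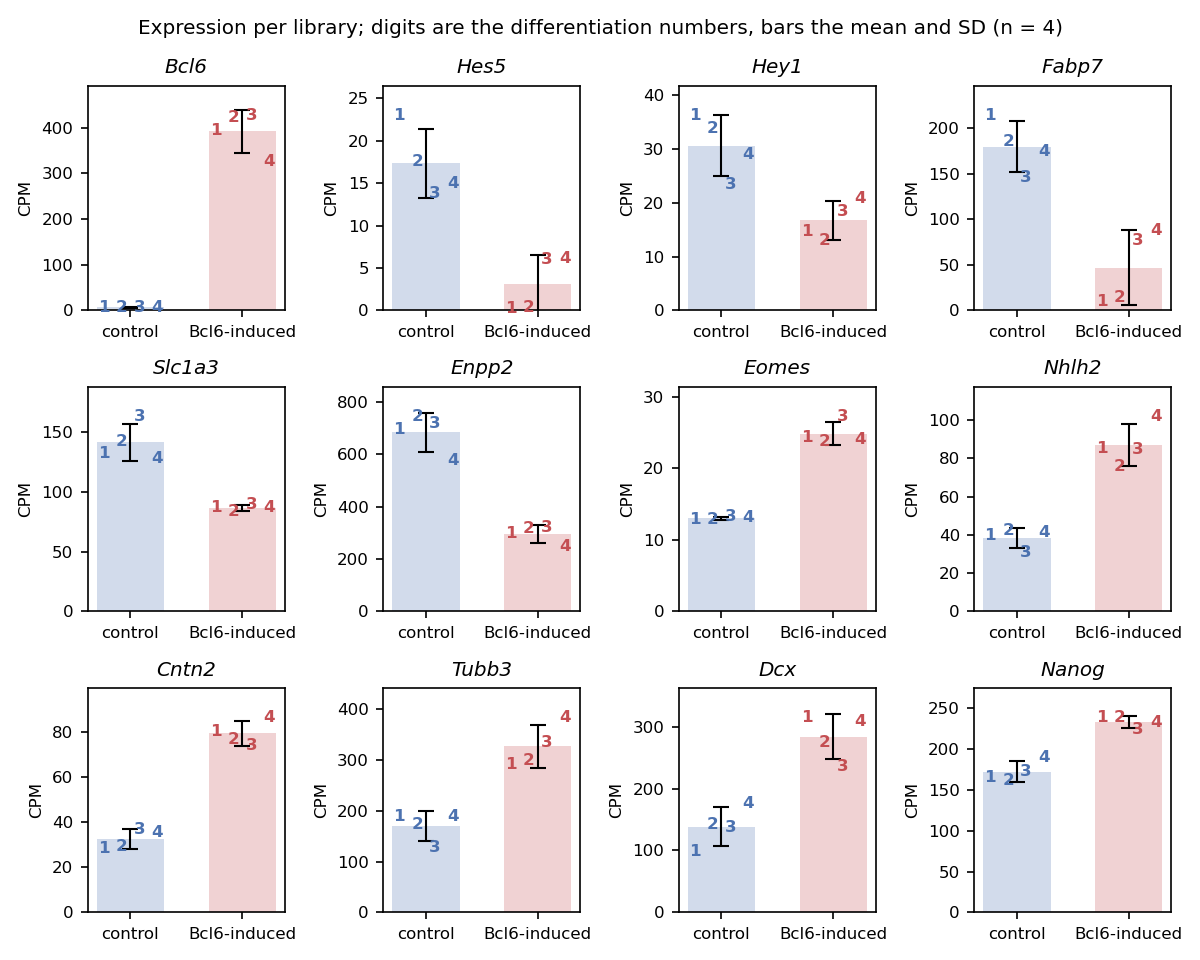
CPM of 12 genes (vertical axes, linear from 0) in the control and Bcl6-induced libraries; digits give each library by its differentiation number, bars the mean and error bars the SD (n = 4). Bcl6 is near 6.49 CPM in the controls and 392 CPM after induction, the error bar of Hes5 is cropped at 0, and Hes5 and Fabp7 are lowest in induced libraries 1 and 2.

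Of 18 measured markers of cortical radial glia and apical progenitors, 9 fell, 1 rose and 8 did not pass the test, and the count was the same adjusted over the list alone. The glutamate transporter Slc1a3 (chromosome 15, 8634124 to 8710764) fell from 141.3 ± 15.6 to 86.6 ± 2.28 CPM (log2 fold change -0.70 ± 0.08, adjusted p = 0.0018). The membrane protein Prom1 fell from 132.8 ± 10.3 to 84.4 ± 13.1 CPM (-0.66 ± 0.11, adjusted p = 0.0069). The member that rose was Lhx2, a homeobox gene of the cortical primordium, from 5.45 ± 0.93 to 11.7 ± 1.01 CPM (adjusted p = 0.0028). Sox2, the general neural progenitor factor, was at 257.1 ± 22.3 CPM in the controls and 255.3 ± 15.5 CPM after induction, and Pax6 was at 20.8 ± 2.47 and 15.8 ± 5.68 CPM (adjusted p = 0.97 and 0.23). With array weights, Pax6 was called lower (adjusted p = 0.038). The list as a whole lay below other genes by camera (adjusted p = 1.3e-05; adjusted p = 0.46 with an estimated correlation). The radial glia genes called lower numbered 2, 6 and 4 without controls 2, 3 and 4, and 2 and 3 without induced libraries 1 and 2. Slc1a3, Prom1 and Lhx2 kept their calls without any single library, and the other 7 called members lost theirs without at least 1. The mean level of the list, relative to the control mean on the log2 scale, was -0.85, -0.90, -0.34 and -0.19 in induced libraries 1 to 4, against 0.06, 0.00, -0.13 and 0.06 in controls 1 to 4.

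Among 22 genes of the Notch pathway, 4 fell and none rose: Hes5, the target Hey1, the feedback regulator Nrarp and the ligand Jag1. Hey1 fell from 30.6 ± 5.67 to 16.7 ± 3.57 CPM (log2 fold change -0.88 ± 0.17, adjusted p = 0.015), Nrarp from 6.03 ± 1.33 to 2.68 ± 1.09 CPM (adjusted p = 0.029) and Jag1 from 71.5 ± 9.18 to 52.6 ± 6.38 CPM (adjusted p = 0.041). Hes1, another Notch target, was at 32.3 ± 6.07 CPM in the controls and 29.5 ± 2.36 CPM in the induced cultures (adjusted p = 0.64). Adjusted over the list alone, 6 members were lower and 1 higher. The camera adjusted p was 0.048 for lower expression (adjusted p = 0.59 with an estimated correlation), and it reached 0.15 without induced library 2; 5 of 8 single leave-outs ended this call (controls 2, 3 and 4 and induced libraries 1 and 2). The call was also lost at 5 of 13 other settings with all 8 libraries: a pseudocount of 0.1, median-of-ratios scaling, upper quartile scaling, a minimum mean of 100 scaled reads, and thinned reads. The Notch genes called lower numbered 0 without control 2, induced library 1 or induced library 2, 1 without control 4, 3 without controls 1 or 3 or induced library 3, and 6 without induced library 4. None of the 4 calls held without every single library: the adjusted p reached 0.061 for Hey1 (without control 2), 0.094 for Nrarp (without induced library 2) and 0.14 for Jag1 (without induced library 1), besides the values for Hes5 above. The mean level of the list was -0.80, -0.74, -0.11 and 0.05 in induced libraries 1 to 4 and between -0.06 and 0.10 in the controls.

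Of 38 Wnt pathway genes, 5 fell and 1 rose, and adjusted over the list alone 9 were lower and 5 higher. The secreted inhibitor Sfrp1 fell from 141.6 ± 12.9 to 92.1 ± 3.10 CPM (log2 fold change -0.62 ± 0.08, adjusted p = 0.0024). The ligand Wnt7a (chromosome 6, 91363981 to 91411363) fell from 10.6 ± 1.02 to 4.76 ± 1.49 CPM (adjusted p = 0.0092), while the receptor Fzd8 rose from 7.46 ± 0.65 to 12.9 ± 0.80 CPM (adjusted p = 0.0040). The other 3 that fell were Sfrp2, Rspo1 and Wnt7b, named after their values were seen, with adjusted p values of 0.017, 0.015 and 0.022. Sfrp2, Rspo1 and Wnt7b lost their calls without some single library, with adjusted p values of up to 0.059, 0.059 and 0.077 (each without induced library 1), and Sfrp1, Wnt7a and Fzd8 did not. Without control 1 the Wnt list held 5 higher and 5 lower genes, and the lower ones numbered 3, 2 and 2 without control 2 and induced libraries 1 and 2. Camera gave the list an adjusted p of 0.094, and called it lower in 2 of 8 single leave-outs (induced libraries 3 and 4) and at 1 of 13 other settings.

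Of 21 FGF pathway genes, 2 fell and 1 rose; adjusted over the list alone, 4 were lower and 8 higher. Spry4, a feedback inhibitor of receptor tyrosine kinase signalling, rose from 20.5 ± 3.75 to 41.3 ± 3.58 CPM (log2 fold change 1.024 ± 0.131, adjusted p = 0.0025), whereas Fgfbp3 fell as given above and the receptor Fgfr3 fell from 24.7 ± 1.69 to 16.4 ± 2.33 CPM (adjusted p = 0.014). Camera gave the list an adjusted p of 0.13 towards higher expression. Fgfr3 was lost without 3 single libraries (adjusted p of up to 0.060 without induced library 1), and without control 1 the list held 6 higher and 3 lower genes. Its lower genes ranged from 0 (without control 2) to 3 over single leave-outs. None of 13 Sonic hedgehog pathway genes passed the test over all genes, and 2 were lower adjusted over the list alone (camera adjusted p = 0.078). Without control 1, 1 hedgehog gene was called lower, without induced library 4, 2 were, and 4 were once the trend on transcript length and GC was taken off. Camera called the hedgehog list lower in 3 of 8 single leave-outs (control 1 and induced libraries 3 and 4) and at 3 of 13 other settings. The cultures of both groups had been grown with cyclopamine.

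Of 14 measured genes of basal progenitors and the neurogenic transition, 4 were higher and none lower, or 5 higher adjusted over the list alone. Eomes, a T-box factor listed here for cortical intermediate progenitors (chromosome 9, 118478212 to 118486132), rose from 13.03 ± 0.257 to 24.9 ± 1.63 CPM (log2 fold change 0.93 ± 0.09, adjusted p = 0.00051). Eomes was at 24.3, 23.8, 27.3 and 24.1 CPM in induced libraries 1 to 4. Which cells of the cultures expressed it was not tested. Nhlh2, a basic helix-loop-helix factor of young neurons, rose from 38.5 ± 5.25 to 86.9 ± 10.7 CPM (1.18 ± 0.12, adjusted p = 0.00065), as did Neurod1, from 6.90 ± 0.80 to 12.1 ± 1.70 CPM (adjusted p = 0.010). These 3 kept their calls without any single library; the remaining member, Nhlh1, named after its values were seen, did not (adjusted p = 0.036, and up to 0.087 without induced library 3). Neurog2, the main proneural factor of the cortex, was at 16.7 ± 3.81 CPM in the controls and 17.7 ± 6.12 CPM after induction (adjusted p = 0.94), with 12.8, 12.3, 21.1 and 24.6 CPM in induced libraries 1 to 4. Camera gave the list an adjusted p of 0.0015 (adjusted p = 0.47 with an estimated correlation). Its mean level was 0.16, 0.08, 0.71 and 0.85 in induced libraries 1 to 4 and between -0.20 and 0.17 in the controls.

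Of 24 pan-neuronal genes, 9 were higher and none lower, and 15 were higher adjusted over the list alone. The neuronal adhesion molecule Cntn2 rose from 32.5 ± 4.33 to 79.3 ± 5.42 CPM (log2 fold change 1.29 ± 0.10, adjusted p = 0.00017). The neuronal tubulin Tubb3 rose from 169.7 ± 28.9 to 327.1 ± 42.1 CPM (0.96 ± 0.13, adjusted p = 0.0031) and doublecortin, Dcx (chromosome X, 143855842 to 143933311), from 138.4 ± 31.6 to 283.6 ± 36.3 CPM (1.05 ± 0.16, adjusted p = 0.0042). Single leave-outs gave 8 to 13 higher genes, the most without control 1. Of the 9, 8 kept their calls without any single library; the exception was Nefm (adjusted p = 0.021, and up to 0.072 without induced library 1). Camera gave an adjusted p of 1.8e-06 (adjusted p = 0.41 with an estimated correlation), and the list's mean level was 0.74, 0.59, 0.31 and 0.53 in induced libraries 1 to 4. Of 14 genes of cortical projection neuron identity, only Tbr1, a marker of deep-layer neurons, passed the test. Tbr1 rose from 0.71 ± 0.29 to 3.06 ± 0.71 CPM (log2 fold change 2.07 ± 0.30, adjusted p = 0.0041), on 4 to 10 reads per control library. The median of this list was 0.00 and its mean 0.13, while camera pointed lower (adjusted p = 0.83).

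**Figure D3:**
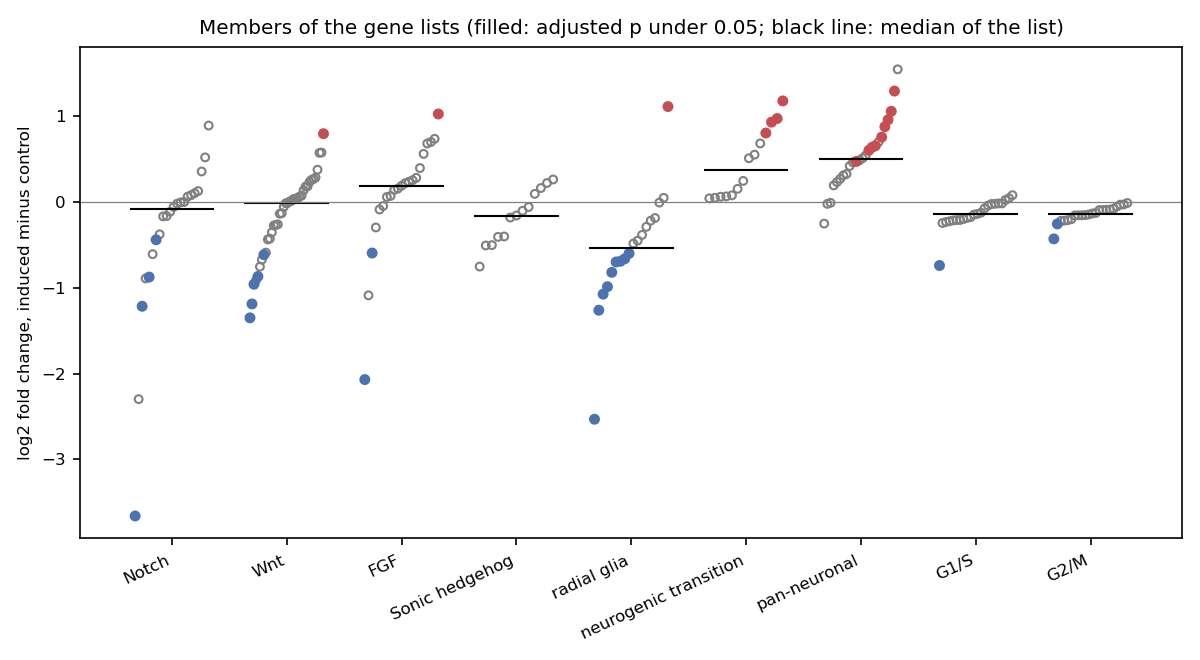
Log2 fold change of every measured member of 9 gene lists (vertical axis, induced minus control); each point is a gene, filled where its adjusted p was under 0.05, and the black line is the list's median. The medians are -0.54 for radial glia markers, 0.38 for the neurogenic transition and 0.50 for pan-neuronal genes.

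Of 22 genes of G1 and S phase 1 fell, the cyclin Ccnd2, from 462.5 ± 75.4 to 284.6 ± 85.9 CPM (adjusted p = 0.045, and up to 0.14 without induced library 1). Ccnd1 was at 144.2 ± 20 CPM in the controls and 92.1 ± 42.3 CPM after induction (adjusted p = 0.12), with 56.5, 56.9, 114 and 141 CPM in induced libraries 1 to 4. Ccnd1 passed the test without induced library 4 (adjusted p = 0.035) and with array weights (adjusted p = 0.020). It also passed with a block for the differentiation number once both libraries of number 3 were left out (adjusted p = 0.015). Of 22 genes of G2 and M phase 2 fell. The spindle protein Nusap1 fell from 269.8 ± 22 to 199.8 ± 8.54 CPM (log2 fold change -0.43 ± 0.07, adjusted p = 0.0087). The kinase Aurkb fell from 125 ± 8.63 to 104.4 ± 2.83 CPM (adjusted p = 0.0498, and up to 0.17 without induced library 1). Mki67, a marker of cycling cells, was at 525.5 ± 152 and 442.9 ± 86.5 CPM (adjusted p = 0.55), and was called lower with the length and GC trend taken off (adjusted p = 0.045). Mki67 was also called lower with a block for the differentiation number once both libraries of number 1 were left out (adjusted p = 0.0043). Without control 1, 3 G1 and S genes and 4 G2 and M genes were lower, and 4 and 7 with that trend taken off. The other single leave-outs gave 0 to 2 and 1. Both lists had a median of -0.14, with camera adjusted p values of 0.00087 and 6.7e-05 (adjusted p = 0.47 and 0.41 with an estimated correlation). Adjusted over each list alone, 2 and 4 members were lower and none higher.

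**Figure D4:**
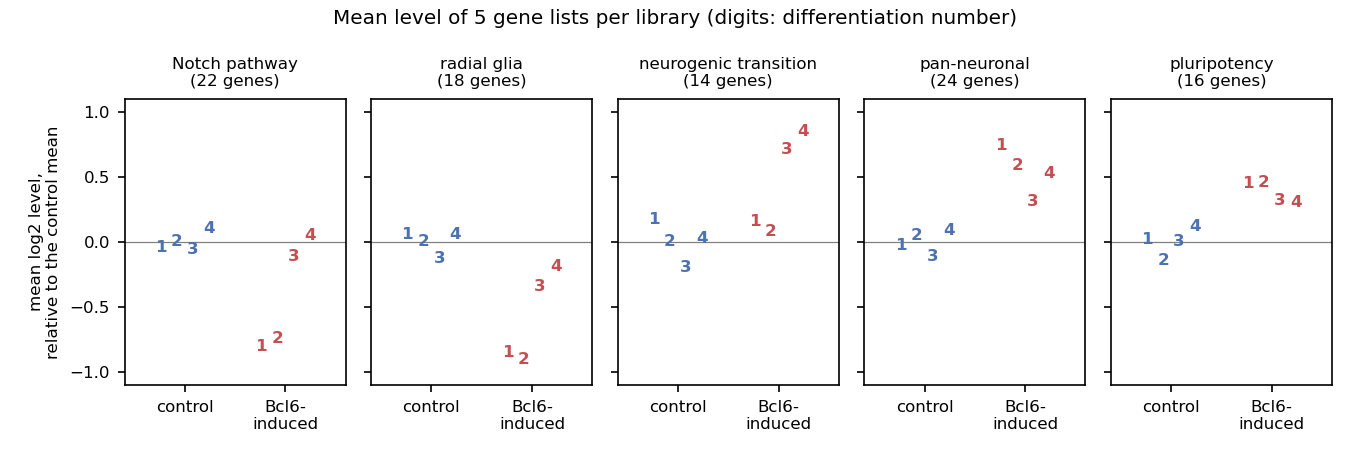
Mean log2 level of 5 gene lists in each library, relative to the mean of the controls (vertical axis); digits are differentiation numbers, controls at the left of each panel. The Notch list is at -0.80 and -0.74 in induced libraries 1 and 2 and at -0.11 and 0.05 in 3 and 4, while the neurogenic list is at 0.16, 0.08, 0.71 and 0.85.

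Of 16 pluripotency genes, listed as a sign of undifferentiated cells, 8 were higher and 1 lower, or 13 and 2 adjusted over the list alone. Lefty2, a secreted inhibitor of Nodal signalling, rose from 40.1 ± 7.53 to 73.3 ± 6.46 CPM (log2 fold change 0.89 ± 0.13, adjusted p = 0.0042), and Nanog from 172.2 ± 13.1 to 233.5 ± 7 CPM (0.44 ± 0.07, adjusted p = 0.0059). The most abundant members did not follow. Tdgf1 fell from 814.8 to 605.1 CPM (-0.43 ± 0.08, adjusted p = 0.012), and Pou5f1 was at 538.2 CPM in the controls and 443.4 CPM after induction (adjusted p = 0.12). Without control 2, induced library 1 or induced library 2, 3 pluripotency genes were higher, without induced library 3, 5 were, and without control 1, 10. Of the 9 called members 4 kept their call without any single library: Lefty2, Nanog, Klf4 and Tdgf1. Camera gave the list an adjusted p of 0.00015 (adjusted p = 0.41 with an estimated correlation).

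Of 9 neural crest and Schwann genes 5 rose, among them the transcription factors Ets1, from 23.7 ± 1.05 to 38.6 ± 2.72 CPM (adjusted p = 0.0020), and Tfap2b, from 30.02 ± 4.44 to 55.3 ± 9.51 CPM (adjusted p = 0.0051), and none fell (camera adjusted p = 0.019; adjusted p = 0.41 with an estimated correlation). Of 14 endoderm genes 3 rose and 1 fell. Krt8 rose from 161.9 ± 22.1 to 236.8 ± 6.95 CPM and Cdh1, the epithelial cadherin, from 250.8 ± 26.6 to 352.6 ± 19.6 CPM (adjusted p = 0.0074 and 0.0081). The third that rose was Krt18 (adjusted p = 0.049, and up to 0.16 without induced library 1). The member that fell was Foxa1, from 24.3 ± 3.29 to 15.8 ± 4.1 CPM (adjusted p = 0.048, and up to 0.15 without induced library 1). Of 12 choroid plexus and cortical hem genes 2 fell, Enpp2, the enzyme autotaxin, from 682.3 ± 74.9 to 295.3 ± 33.1 CPM (log2 fold change -1.21 ± 0.10, adjusted p = 0.00024), and Otx2, from 218.5 ± 14.7 to 160.8 ± 5.10 CPM (adjusted p = 0.0055). The other lists of this kind had at most 2 calls each. Lmx1b rose among 10 caudal markers, from 17.97 ± 3.06 to 31.9 ± 2.15 CPM, and Acta2, a smooth muscle actin, among 15 fibroblast markers, from 75.7 ± 15.5 to 149.4 ± 14.5 CPM (adjusted p = 0.0035 and 0.0033). Mbp rose from 37.9 ± 3.55 to 55.9 ± 2.65 CPM and Aldoc fell from 64.0 ± 5.58 to 44.4 ± 8.41 CPM among 7 astrocyte and oligodendrocyte genes. Crx rose among 6 retinal genes, from 0.78 ± 0.22 to 2.53 ± 1.41 CPM, and Tek fell among 7 endothelial and blood genes, from 24.6 ± 2.53 to 16.3 ± 3.12 CPM. None of 14 ventral telencephalic and GABAergic genes passed the test. Aldoc, Crx and Tek lost their calls without some single library (adjusted p of up to 0.089, 0.13 and 0.093), and Ets1, Tfap2b, Krt8, Cdh1, Enpp2, Otx2, Lmx1b, Acta2 and Mbp did not.

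Of 23 BMP and TGF-beta genes 5 rose and none fell, led by Bmp7, from 31.8 ± 2.76 to 46.8 ± 2.42 CPM, and the antagonist Fst, from 24.4 ± 0.98 to 33.97 ± 1.95 CPM (adjusted p = 0.0047 and 0.0087). Camera gave an adjusted p of 0.048 (adjusted p = 0.47 with an estimated correlation). Among 15 retinoic acid genes the binding protein Crabp1 rose from 40.5 ± 8.34 to 80.8 ± 6.85 CPM (adjusted p = 0.0028), and Dhrs3 and Cyp26b1 fell, Dhrs3 from 10.4 ± 1.86 to 5.85 ± 0.70 CPM (adjusted p = 0.013, and 0.053 without induced library 1). Cyp26b1 (adjusted p = 0.028) kept its call in only 3 single leave-outs, with an adjusted p of up to 0.083 without induced library 2. Of 16 genes of the IGF and PI3K pathway 1 fell, Igfbp2, from 613.1 ± 84.2 to 447.0 ± 19.7 CPM (adjusted p = 0.019, and up to 0.063 without induced library 1). Of 16 genes that Bcl6 represses in B cells, 2 were called and both were higher, Prdm1, from 22.7 ± 3.43 to 33.3 ± 1.78 CPM, and Socs2, from 33.9 ± 3.00 to 43.0 ± 1.55 CPM (adjusted p = 0.018 and 0.036, and up to 0.073 and 0.11 without single libraries). Adjusted over the list alone 3 were higher and 5 lower. Of 17 Bcl6 partner genes 1 fell, the deacetylase Hdac5, from 297.6 ± 26.9 to 213.7 ± 20.9 CPM (adjusted p = 0.014). Among 7 genes beside Hprt, the usual site of the inducible cassette in this kind of cell line, Phf6 fell from 123.2 ± 15.4 to 95.7 ± 5.20 CPM (adjusted p = 0.043, and up to 0.14 without induced library 2).

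Of 15 p53 and apoptosis genes 2 rose, the death receptors Tnfrsf10b, from 25.2 ± 3.19 to 35.1 ± 4.80 CPM, and Fas, from 1.48 ± 0.34 to 2.87 ± 0.72 CPM, and their calls were lost without 5 and 7 of the 8 single libraries (adjusted p = 0.042 and 0.046 with all libraries, up to 0.14 and 0.17 without induced library 1). Without control 1, 5 genes of this list were higher. Camera gave an adjusted p of 0.0034 (adjusted p = 0.47 with an estimated correlation). Of 14 immediate early and heat shock genes 3 rose, led by Junb, from 12.3 ± 2.70 to 22.5 ± 2.95 CPM, and Nr4a1, from 14.9 ± 1.16 to 20.6 ± 1.94 CPM (adjusted p = 0.012 and 0.029; camera adjusted p = 0.048; adjusted p = 0.47 with an estimated correlation). Of 16 interferon response genes 3 rose, led by Ifit1, from 2.81 ± 0.95 to 6.10 ± 0.65 CPM, and Rsad2, from 4.07 ± 1.27 to 7.53 ± 0.91 CPM (adjusted p = 0.014 and 0.029; camera adjusted p = 0.0047; adjusted p = 0.47 with an estimated correlation). Of 16 genes of the integrated stress response, Trib3 rose from 8.76 ± 0.72 to 13.1 ± 1.44 CPM (adjusted p = 0.022), while Psat1 and Phgdh fell, Phgdh from 244.9 ± 35.1 to 172.9 ± 9.17 CPM (adjusted p = 0.015). None of 10 mitochondrially encoded transcripts passed the test. Of these genes only Junb kept its call without any single library. The adjusted p reached 0.096 for Nr4a1, 0.055 for Ifit1, 0.10 for Rsad2, 0.085 for Trib3 and 0.060 for Phgdh.

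Adjusted over each list alone, the neural crest genes numbered 5 higher and 1 lower, and the endoderm genes 5 higher and 2 lower (camera adjusted p = 0.11). Choroid plexus and hem genes numbered 3 lower (camera adjusted p = 0.057), and interferon genes 6 higher. Genes of p53 and apoptosis numbered 4 higher, immediate early genes 3 higher, and BMP and TGF-beta genes 6 higher and 1 lower. Retinoic acid genes numbered 1 higher and 3 lower, IGF and PI3K genes 2 lower, and integrated stress genes 3 higher and 2 lower. Endothelial and blood genes numbered 4 higher and 1 lower, astrocyte and oligodendrocyte genes 3 higher and 1 lower, and fibroblast genes 1 higher and 2 lower (camera adjusted p = 0.070, 0.17 and 0.83). Camera gave 0.14 for retinal genes, 0.12 for mitochondrial transcripts, 0.38 for the B-cell targets of Bcl6 and 0.83 for its partner genes. Median, mean and camera direction also differed in sign for the retinoic acid, IGF and PI3K, integrated stress, ventral, caudal and Hprt lists (camera adjusted p = 0.71, 0.83, 0.89, 0.83, 0.62 and 0.73). The camera calls of the BMP and TGF-beta list and the immediate early list were lost without 5 and 6 single libraries, with an adjusted p of up to 0.12 (without control 3) and 0.093 (without induced library 2). Camera called the choroid plexus and hem list in 3 single leave-outs and at 3 other settings, the endothelial and blood list in 2 and at 2, the endoderm list in 2 leave-outs and the mitochondrial list in 1. Over single leave-outs, the higher genes ranged from 2 to 7 for BMP and TGF-beta, 0 to 4 for interferon, 1 to 4 for immediate early, 3 to 5 for neural crest, 2 to 3 for endoderm, 0 to 3 for integrated stress and 0 to 2 for B-cell targets of Bcl6 (lower, 0 to 2). The BMP, immediate early, integrated stress and neural crest counts were highest without control 1, and the interferon count without control 1 or control 3. The higher neurogenic genes ranged from 3 to 4, and in lists whose leave-out counts are not given no count passed 2.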

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

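Of 142 sets of 4 values (70 named genes and the recovered read totals, each in 2 groups), 7 had a library far from the other 3, where about 7.1 would be expected by chance. Cdx2 was low in control 2, at 0.451 CPM against 1.5 to 1.66 in the other controls. Igfbp2 was high in control 1, at 738 CPM against 564 to 586, and Lmx1b in control 4, at 22.6 CPM against 16.3 to 16.7. Among induced libraries, Eomes was high in library 3, at 27.3 CPM against 23.8 to 24.3, and Phgdh in library 3, at 186 CPM against 167 to 170. Junb was low in induced library 4, at 18 CPM against 23.6 to 24.2, and so was Sox2, at 232 CPM against 262 to 264.

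The tests in this part were chosen after the results they bear on had been seen, except the count of gene lists over other splits. The number of changed genes is unlikely to be a chance result of how the 8 libraries, taken without their numbers, were grouped. Only 1 of 35 splits into 4 and 4, the real one, gave as many as 1019 genes by limma, and the highest other gave 0, with 2135 genes at an unadjusted p under 0.05 against 3547. This is the lowest share the test can reach. With a block for the number, the real split gave 827 genes and the others that part every same-numbered pair gave 0. Those splits number 8 with the real one, too few to reach a share under 0.05, so the blocked version cannot decide. For the number of gene lists called by camera chance cannot be excluded: 6 of 35 splits gave at least the 12 lists of the real one, and the highest other gave 14.

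Control 1 stood apart from the other controls. Transcript length and GC content may account for most of this: 53% of the variance of its deviations followed them, against 16.5%, 25.9% and 28.4% in controls 2, 3 and 4. With that trend taken off every control, its excess of SD over the next control fell from 0.075 to 0.013. An induced culture under a control label is argued against by Bcl6, at 6.61 CPM in control 1. What in the culture or library gave the trend stays open, and no biological explanation was tested.

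Radial glia genes lay at different levels in the 4 induced libraries, over a range of 0.71 (log2). Depth is argued against, since the range was 0.67 with all libraries thinned to the smallest. The controls differed less among themselves, over a range of 0.19. Since numbers were not taken as pairs, the controls need not give the level of these induced cultures before induction. A difference already present without induction therefore stays open. The amount of Bcl6 mRNA may matter, which stays open: in 4 of 6 pairs of induced libraries the one with more Bcl6 had the lower level (exact one-sided p = 0.375, where 4 libraries can reach 0.042 one-sided and 0.083 two-sided).

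Of 16 pluripotency genes, 8 were higher in the induced cultures. A larger share of undifferentiated cells stays open: the other 14 members were all positive, with a median of 0.47, but the most abundant, Tdgf1 and Pou5f1, had a mean log2 fold change of -0.35 ± 0.09 (SE), a direction already seen when they were picked. Scaling is argued against, with a median of 0.39 under upper quartile scaling against 0.44. Doxycycline itself may have contributed, which stays open because 0 libraries of doxycycline-treated cultures without the transgene were available.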

How the results depend on the processing

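The planned edgeR and DESeq2 alternatives were not run, because the values are not raw counts, and the planned minimum mean of 1 removes no gene. Other scalings, higher filters, variance models, array weights, thinned reads and removal of the length and GC trend were chosen after seeing the data. No gene called changed turned its direction at any setting. Of 64 named genes called, 36 kept the call without any 1 library and 49 at all other settings with the same 8 libraries. Other thresholds move the counts by construction; for all other moves, the leave-outs included, the cause was not tested. Over all leave-outs, changed genes ranged from 46 to 1697 (main 1019), higher from 33 to 1146 (681) and lower from 13 to 551 (338), the lowest without both libraries of number 2. Counts were 2507 (1643 higher, 864 lower) with array weights and 1762 (863 lower) with the length and GC trend removed. Without a variance trend 225 were lower. At an adjusted p under 0.01 they were 227 (163 and 64), under 0.1 1836 (1194 and 642), and with a log2 fold change of at least 1 166 (93 and 73). Camera called 0 lists with an estimated correlation (main 12). A replicate block gave 827 genes, 740 shared, called 2 Sonic hedgehog genes lower (main 0), and ended the camera calls of the BMP and TGF-beta and immediate early lists (adjusted p = 0.08 each) and the limma calls of Aurkb, Socs2, Phf6, Tnfrsf10b and Fas (adjusted p = 0.099, 0.063, 0.063, 0.059 and 0.056). With it they were 61 (45 and 16) without number 2, 387 (251 and 136) without number 4, and 517 lower without number 1. The plan had fixed a main test without a block, and numbers were not taken as pairs. In the pairing check, same-numbered libraries correlated at 0.03, 0.01, -0.03 and 0.37, and not every library correlated best with its own number. The check used deviations from the group means, which hold the length trend of control 1, so it cannot show that same-numbered cultures were unpaired. Genes not called could turn: Sox2 (main -0.01) ranged from -0.058 to 0.05 over leave-outs, with 0.054 under array weights and, with the block, 0.033 and 0.018 without numbers 1 and 4. Neurog2 (main 0.04) ranged from -0.156 to 0.322, with -0.011 under upper quartile scaling, -0.034 under array weights, -0.009 with the trend removed and, with the block, -0.149 and -0.156 without numbers 3 and 4. Depth limits genes with few reads, such as Hes5 with 3 reads in each of induced libraries 1 and 2.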

Other observations

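The genes in this part were chosen after their values were seen, from the 12 smallest p-values outside the naming rule and the gene lists, and form no tested group. All kept their call by limma without any single library. T (brachyury), the T-box factor of the primitive streak (chromosome 17, 8434423 to 8442496), rose from 20.9 ± 3.13 to 59.9 ± 2.29 CPM (SD, n = 4; adjusted p = 0.00011). Tfap2c, a factor of trophectoderm and germ cells, rose from 34.7 ± 1.75 to 76.6 ± 5.73 CPM (adjusted p = 0.00011). Scrt1, a zinc finger repressor of young neurons, rose from 11.8 ± 0.92 to 28.7 ± 1.34 CPM (adjusted p = 0.00015), and the axon guidance receptor Robo3 from 17.2 ± 1.76 to 47.3 ± 10.8 CPM (adjusted p = 0.00064).

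The netrin receptor Unc5b rose from 78.3 ± 3.47 to 156 ± 18.9 CPM and the growth factor Pdgfb from 9.64 ± 1.27 to 22.8 ± 1.17 CPM (both limma adjusted p = 0.00043, n = 4). Dusp4, a phosphatase of MAP kinases, rose from 54.9 ± 5.5 to 107.3 ± 3.43 CPM (adjusted p = 0.00024). Cyp1a1, the main target of the aryl hydrocarbon receptor, rose from 0.43 ± 0.21 to 5.61 ± 0.85 CPM (adjusted p = 0.00026), and Fam46a fell from 77.7 ± 8.99 to 33.2 ± 2.15 CPM (adjusted p = 0.00016).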
